A study of Mus musculus with 3 samples.

How the data were processed

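Single-cell RNA sequencing libraries were made with the 10x Genomics Chromium 3' kit (version 3.1) from mouse trunks between the neck and the upper thorax, with limbs and thoracic organs taken away, per the labels' protocols. There is 1 library each for embryonic days (E) 11.5, 12.5 and 13.5, and each library is a pool of cells from 3 littermates dissociated with TrypLE, so each stage has 1 replicate. The deposited matrices hold UMI counts per gene and barcode, not normalised, made by the authors with Cell Ranger 8.0.1 on the mouse build GRCm39, per the submitters' processing notes and the file headers. The annotation release is not given in the sources used here. The reference at hand was of another build, so no coordinates were used, and genes are named by the symbols in the files. Symbols shared by several gene identifiers (26) were kept apart by identifier.

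The matrices list every barcode, empty droplets included. A barcode was taken as a cell when its UMI total reached the 99th percentile of the expected cells divided by 10, with at least 500 genes and at most 10% mitochondrial UMIs. The UMI minimum came to 4073 at E11.5, 4046 at E12.5 and 3359 at E13.5, and 6330, 6193 and 7776 barcodes reached it. The gene filter left 6330, 6158 and 7345 barcodes and the mitochondrial filter 6309, 6132 and 7236. Doublets were called per library with scrublet in scanpy 1.11.5, at its automatic threshold, which marked 159, 125 and 192 barcodes (2.52, 2.04 and 2.65%). Called doublets were removed after clustering, together with 101, 12 and 2 further cells of 1 cluster made mostly of called doublets. This left 6049, 5995 and 7042 cells, with median depths of 12262, 10942 and 10073 UMIs.

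Cells of the 3 libraries were clustered together without integration (3000 variable genes, 40 principal components, 15 neighbours, Leiden clustering with igraph 0.11.9 at resolution 1). Sox9 and the haemoglobin, mitochondrial, ribosomal protein, Xist and Y-linked genes were kept out of the variable genes, so that the Sox9 level of a class was not set by the clustering. Mesenchymal clusters, those with Pdgfra in at least 30% of cells that were unnamed or named for a mesenchymal class, were clustered again at resolution 2. Clusters were named from 164 markers of 27 classes. A name needed at least 3 markers at 2 times the level of the other cells or more and found in at least 5% of the cluster's cells, and a cluster stayed unnamed where its 10 leading genes held more markers of another class than of its own. At the second level the 10 genes with the highest fold also had to hold at least 1 marker of the class. Of 34 clusters at the first level 30 were named and 13 were mesenchymal. Of 34 mesenchymal sub-clusters 13 were named. The number of clusters with over 90% of cells from 1 library was 11 at the first level and 20 at the second, and such a cluster may be that library rather than a cell type.

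The cell filter, the markers, the gene lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. Other choices were made after seeing the data. These are the second level of clustering and its resolution, the naming thresholds and the Pdgfra rule. They also include leaving a cluster led by mast cell proteases unnamed, the droplets read as background (50 to 500 UMIs) and the removal of doublets after clustering. The demand for a class marker among the 10 leading genes was set after the Sox9 shares of the sub-clusters it parts had been seen. It kept 1 sub-cluster out of the brown adipose precursor-like class and 2 out of the dermal-like class. Shares are given with and without them, and Sox9 values with and without the first. The comparison of Ebf2-positive cells, the comparison of cells with Xist, the stage comparisons with 1 class or 1 myocyte-like cluster left out and the counts of marker combinations were also added later. So were the fits without sclerotome-like cells, without clusters named chondrogenic at the first level and in Ebf2-positive cells alone.

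Levels are in CPM, the summed UMIs of a gene in a class scaled to the class's total, with exact Poisson intervals. Shares have exact Clopper-Pearson intervals, and beside a class share of 0 stands the share that 3 cells would make. Log2 ratios between adjacent stages have exact conditional binomial intervals. Ratios under an alternative, free RNA subtraction included, were made with 0.5 UMIs added to each count, so that one over 0 UMIs is set by that addition. These intervals are at 95% and cover counting error only. A stage comparison was made where both libraries held at least 50 cells of the class. The remaining mesenchyme is all mesenchymal cells outside the chondrogenic-like and brown adipose precursor-like classes. For shares of cells with a UMI, each mesenchymal cell was thinned to 4000 UMIs and shallower cells were left out, which removed 51 cells at E13.5 and 0 at the other stages. The share of free RNA was estimated per library from haemoglobin UMIs outside erythroid-like cells.

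Sox9-positive (at least 1 UMI after thinning) and Sox9-negative mesenchymal cells outside the chondrogenic-like and tendon-like classes were summed per library. The 6 sums were tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr, Benjamini-Hochberg adjustment over 12197 genes, Sox9 left out), with the library as a block, since both sums of a pair come from the same cell suspension. Gene lists were tested with camera in limma 3.58.1 (R 4.3.3), with its preset correlation and with an estimated one. The same contrast within the brown adipose precursor-like class needed 20 cells per sum in at least 2 libraries and was not made.

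The 25 gene lists hold 351 entries, of which 4 have a symbol that the matrices do not list. They cover brown adipose regulators, adipocyte differentiation, thermogenic genes, chondrogenesis, osteogenesis, tendon, dermomyotome and dermis, sclerotome, lateral plate, myogenesis, 3 groups of Hox genes, matrix, S phase, G2 and M phase, immediate early genes, heat shock, hypoxia and glycolysis, Hedgehog, WNT, BMP and TGF-beta, retinoic acid, IGF and imprinted growth genes, and oxidative phosphorylation. Between stages, a list's median log2 ratio over members with at least 10 UMIs was placed among 10000 random lists of the same size, matched on expression in 20 bins. A member with 0 UMIs in 1 library took the extreme rank.

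Sox9, Ebf2, Pparg, Pdgfra, Gata6, Cebpa and Prdm16 are always named. In the remaining mesenchyme, and in the Ebf2-positive cells added later, the 10 genes with the highest and the 10 with the lowest ratio are named (5 and 5 in other classes), among genes with at least 100 UMIs, an interval that excludes 0 and at most 25% of the higher count accounted for by free RNA. In the Sox9 contrast these are the 10 with the highest and the 10 with the lowest fold change among genes with an adjusted p under 0.05, the same sign in each library and a mean of at least 20 CPM. Up to 4 members of a list with the largest absolute difference are named. Predicted, Riken, haemoglobin, mitochondrial, ribosomal protein and sex-linked marker genes were left out of the naming. Some genes that meet these rules are not reported here.

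The statistics were tested on simulated data. For E13.5 against E12.5 in the remaining mesenchyme, 95.4% of the true ratios of 13134 genes lay inside the interval. The interval excluded 0 for 100% of the genes changed by 1 on the log2 scale and for 91% of those changed by 0.5. Of unchanged lists 4.6% lay outside the middle 95% of random lists, over 17364 genes. Counts for these stage ratios and lists were drawn gene by gene from a Poisson distribution, so members of a list did not vary together. The simulation therefore cannot say how the percentiles behave for lists whose members do. The interval of a ratio assumes the same distribution, so coverage near 95% follows from the draw. How the interval behaves where the UMIs of a gene gather in few cells was not tested. For the Sox9 contrast, edgeR recovered 75% of genes changed by 1 and 38% of those changed by 0.5, with 8.13% of its calls false, over 12197 genes.

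Alternatives were another cell filter (2000 UMIs and 1000 genes), a mitochondrial maximum of 5%, doublets kept, clustering without marker and co-detection genes, each library clustered alone, resolution doubled, TMM scaling and subtraction of free RNA. For the shares they were thinning to 2000 UMIs and no thinning, and for the lists a minimum of 100 UMIs. For the Sox9 contrast they were DESeq2 1.42.0, its size factors in edgeR, no filter, no block, each library left out, thinning to 2000 UMIs and 2 or more Sox9 UMIs against 0. Analyses ran in Python 3.11.15 with anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, umap-learn 0.5.12 and matplotlib 3.10.9.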

Results

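The trunk of mouse embryos between the neck and the upper thorax, a region where brown adipose tissue forms, was profiled by single-cell RNA sequencing at E11.5, E12.5 and E13.5. The tissue held derivatives of the somites and of the lateral plate, together with the neural tube, and each stage is 1 library from a pool of 3 littermates. The libraries held 103383215, 94155624 and 113402193 UMIs in that order of stage. The cells kept numbered 6049, 5995 and 7042, with median depths of 12262, 10942 and 10073 UMIs and 3571, 3407 and 3136.5 genes. Free RNA was estimated at 2.17% of the UMIs of cells at E11.5, 7.39% at E12.5 and 22.6% at E13.5. Xist was detected in 65.3, 26.8 and 94.9% of cells and Y-linked transcripts in 29.8, 60.6 and 2.41%, so the sex of the pooled embryos differed with the stage. With 1 library per stage, a difference between stages has no replicate check, and intervals cover counting error only.

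The first question was which cell classes each stage held. Sclerotome-like cells, marked by Pax1 and Pax9, made up 13.1% of cells at E11.5 (95% interval 12.2 to 13.9), 0.384% at E12.5 and 0 of 7042 cells at E13.5, which allows a share of up to 0.0426%. An unnamed sub-cluster led by Pax9, Pax1 and Foxd1, with fewer than 3 markers of the class, held a further 0.0331, 3.84 and 2.54% of cells, so cells with these genes were found at each stage. Chondrogenic-like cells (Col2a1, Col9a1) were 0.0496% at E11.5, 4.89% at E12.5 and 1.12% at E13.5, and tendon-like cells (Scx, Tnmd) 0.0496, 4.05 and 1.89%. Dermal-like cells (Dpt, Lum) were 0 of 6049 cells at E11.5, 0.367% at E12.5 and 13.7% at E13.5, or 0.567 and 20.97% at the last 2 stages with the sub-clusters led by Nrgn and by Cemip. Brown adipose precursor-like cells (Ebf2, Pparg, Cebpa and other markers) were 0 of 6049 at E11.5, which allows up to 0.0496%, 0.400% at E12.5 (0.257 to 0.595) and 7.44% at E13.5 (6.84 to 8.08). The name rests on the E13.5 cells. At E12.5 the 24 cells held 0 Pparg UMIs (up to 13.05 CPM), against 42.3 CPM at E13.5, and no Cebpa UMI after thinning. The sub-clusters led by Nrgn and by Cemip, and a neighbouring one led by Mfap5, Ren1 and Clec3b, were kept out of their classes by a rule set after seeing the data. The last held 0, 0 and 5.40% of cells, and with it the E13.5 share was 12.8% (12.1 to 13.6). Intervals do not cover the clustering, on which these shares depended. At the first level of clustering, clusters named dermal held 10.1% of cells at E12.5 and 24.2% at E13.5, and the cluster named brown adipose precursor 1.13 and 21.4%. Clusters named tendon held 26.2 and 14.2% there, and clusters named chondrogenic 9.64 and 5.37%, above the shares of those classes. The E13.5 share of brown adipose precursor-like cells was 1.70% with called doublets kept, 1.62% with each library clustered alone and 3.72% with resolution doubled. At E12.5 it was 0.134% at a 5% mitochondrial maximum, 0.0815% with doublets kept and 0% with each library alone. Sclerotome-like cells ranged over the other settings from 1.88 to 4.34% at E12.5 and from 0.682 to 4.22% at E13.5, and were 5.19% at E11.5 with each library alone. At the second level, tendon-like cells at E12.5 ranged from 0.04997 to 8.41%, chondrogenic-like cells were 1.42, 2.97 and 2.19% with each library alone, and dermal-like cells at E13.5 were 25.4% at a 5% mitochondrial maximum.

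Muscle-like cells were 5.41, 7.26 and 9.20% of cells, of which myogenic progenitor-like cells were 4.10, 4.27 and 5.38% and myocyte-like cells 1.31, 2.99 and 3.82%. Neural progenitor-like cells had shares of 21.5, 9.22 and 1.11%, and spinal neuron-like cells 17.7, 14.3 and 2.36%. A cluster led by Tlx3, Drgx and Lmx1b, with 5 markers of spinal neurons but sensory neuron markers among its leading genes, stayed unnamed (0.331, 7.26 and 4.43%), and with it the spinal neuron-like shares were 18.02, 21.5 and 6.79%. Macrophage-like cells were 0.678, 1.38 and 4.005%, epidermis-like cells 1.29, 1.59 and 4.18%, and mesothelium-like cells 5.24, 0.334 and 0.0852%. Meningeal-like cells were 1.75, 3.07 and 1.92%. With the other cell filter myocyte-like cells were 5.17, 8.004 and 8.81%, without marker genes mesothelium-like cells at E11.5 were 14.55%, and at double resolution spinal neuron-like cells at E11.5 were 8.98%. Mural-like cells were 0.198, 0.350 and 0.937%, endothelial-like cells 0.926, 0.517 and 1.14%, Schwann- and neural crest-like cells 2.55, 1.301 and 2.05%, sympathetic neuron-like cells 0.364, 0.417 and 0.454%, and erythroid-like cells 2.17, 3.20 and 1.89%. At E13.5 the gene filter left 7345 of 7776 barcodes, and the class of those removed is not known. Shares of classes with few genes per cell may therefore be understated there. Mesenchymal cells without a name were 25.2, 38.1 and 40.9%, and other cells without one 1.92, 8.89 and 5.68%. Dissection can set how much neural tube and skin each pool held, and 20 of 34 mesenchymal sub-clusters drew over 90% of their cells from 1 library. The brown adipose precursor-like class was a single sub-cluster at both stages. The tendon-like class lay mostly in sub-cluster 11 at E12.5 (95.5%) and in sub-cluster 26 at E13.5 (77.4%), the meningeal-like class in sub-cluster 6 at E11.5 and in sub-cluster 25 later (58.2 and 69.6%), and the chondrogenic-like class in sub-cluster 17 at E12.5 (60.1%) and E13.5 (70.9%).

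The study names SOX9, a transcription factor required for cartilage formation, as part of a marker of early brown adipose tissue, so its transcript was compared between classes. Sox9 was highest in chondrogenic-like cells, at 808.7 CPM at E12.5 (95% interval 782 to 836) and 474.2 at E13.5 (428 to 524). Sclerotome-like cells held 403.6 CPM at E11.5 (392 to 415) and neural progenitor-like cells 358.4, 416.9 and 339.5 CPM at the 3 stages. Brown adipose precursor-like cells held 95.5 CPM at E12.5 (62.9 to 139, 24 cells) and 193.9 at E13.5 (182 to 206, 524 cells). Tendon-like cells were at 109.1 and 75.4 CPM at E12.5 and E13.5, and dermal-like cells at 40.3 CPM at E13.5. Meningeal-like cells were at 104.3, 76.3 and 42.5 CPM, and unnamed mesenchyme at 168.3, 107.1 and 67.2 CPM. Lower levels were found in myogenic progenitor-like cells (42.7, 13.7 and 12.98 CPM), spinal neuron-like cells (26.8, 7.87 and 4.60) and macrophage-like cells (24.04, 9.03 and 1.37). The droplets without a cell held Sox9 at 88.7, 58.2 and 29.99 CPM.

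**Figure D1:**
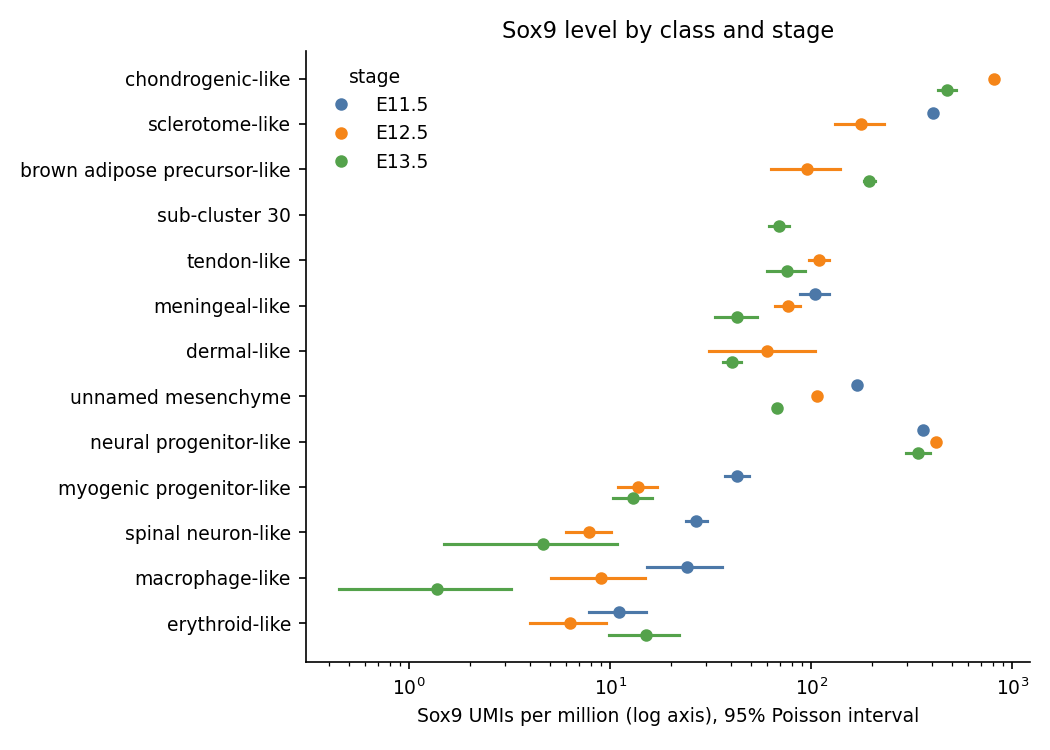
Sox9 level (CPM of UMIs) of selected cell classes with at least 20 cells, by stage, with exact Poisson 95% intervals for counting error. Some classes of that size, mesothelium-like cells among them, are not drawn. The unnamed sub-cluster led by Mfap5 and Clec3b is drawn beside the classes. Chondrogenic-like cells at E12.5 stand highest at 808.7, and brown adipose precursor-like cells at E13.5 stand at 193.9. The level of the other mesenchyme at E13.5, 68.2, is not drawn.

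Within each library, Sox9 in brown adipose precursor-like cells was then set against all other mesenchymal cells. At E13.5 it was higher, 193.9 against 68.2 CPM, a log2 ratio of 1.51 (95% interval 1.40 to 1.61). At E12.5 it was lower, 95.5 against 184.0 CPM, a log2 ratio of −0.95 (−1.55 to −0.40) that rests on 24 cells and 27 Sox9 UMIs. When chondrogenic-, tendon- and sclerotome-like cells, which include the mesenchyme richest in Sox9, were left out of the comparison group after seeing the data, the E12.5 ratio was −0.13 (−0.73 to 0.42) and the E13.5 ratio 1.68 (1.58 to 1.79). That group still held an unnamed sub-cluster led by Pitx1 and Runx1 (151 cells at E12.5), with Sox9 in 68.2% of its cells before thinning. The E12.5 ratio therefore still depends on which cells it is set against. The sub-cluster led by Mfap5 and Clec3b held 69.1 CPM, a log2 ratio of 0.02 (−0.16 to 0.20), and with it the E13.5 ratio of the class was 1.03 (0.93 to 1.12). After thinning to 4000 UMIs, 44.7% of the class had a Sox9 UMI at E13.5 (40.4 to 49.1), and 65.3% did before thinning. The class was not compared between stages, since E12.5 held fewer than 50 of its cells. It had 233 Sox9-positive and 288 Sox9-negative thinned cells at E13.5, 9 and 15 at E12.5 and none at E11.5, so only 1 library could enter a test within the class and none was made.

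The combination of Sox9 with genes of the adipose lineage was followed in single mesenchymal cells, each thinned to 4000 UMIs. Ebf2 encodes a factor that marks and directs brown adipose precursors. Among Ebf2-positive cells, 38.5% had Sox9 at E11.5 (95% interval 34.55 to 42.6) against 40.8% of Ebf2-negative cells, and 24.8% against 27.3% at E12.5. At E13.5 the share was higher in Ebf2-positive cells, 27.3% (25.05 to 29.65) against 15.85% (14.6 to 17.2). Pparg encodes the main regulator of fat cell differentiation. Of the 140 Pparg-positive cells at E13.5, 49.3% had Sox9 (40.7 to 57.9) against 18.6% of the others, while E12.5 held 6 Pparg-positive cells and E11.5 none. Cebpa, its partner in fat cell differentiation, gave 37.85% (31.3 to 44.7) against 18.6% at E13.5, 23.3 against 26.6% at E12.5, and 50% of 12 cells against 40.2% at E11.5.

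Gata6 encodes a factor used in early brown adipose precursors. Among Gata6-positive cells the share with Sox9 was lower at E11.5, 27.5% (19.4 to 36.9) against 40.8%, and higher at E13.5, 28.5% (25.1 to 32.1) against 18.0%, with 28.05 against 26.4% at E12.5. For Pdgfra, a receptor of mesenchymal progenitors, the shares were 42.9 against 38.9%, 23.7 against 28.9% and 19.8 against 19.3%. For Prdm16, which maintains brown fat identity, they were 50.4 against 39.6%, 36.5 against 26.2% and 30.6 against 19.2%. Cells with both Ebf2 and Gata6 had Sox9 in 42.3% of 175 cells at E13.5 (34.9 to 49.97), and cells with both Ebf2 and Pdgfra in 41.8, 22.75 and 27.7% at the 3 stages. Cells with Sox9, Ebf2 and Pdgfra together made up 3.67, 3.45 and 3.58% of mesenchymal cells, Sox9 with Ebf2 9.31, 7.81 and 8.69%, Sox9 with Pdgfra 14.3, 10.8 and 7.615%, Sox9 with Gata6 1.24, 2.02 and 4.05%, and Sox9 with Pparg 0 (at most 0.152), 0.1301 and 1.48%. In a count added after seeing the data, Pparg was found at E13.5 in 8.40% of cells with Sox9 and Ebf2, 6.94% with Sox9 alone, 3.53% with Ebf2 alone and 1.23% with neither. Within the brown adipose precursor-like class the order differed, with Pparg in 12.4% of cells with Sox9 and Ebf2, 29.2% with Sox9 alone (19.05 to 41.1), 11.3% with Ebf2 alone and 8.11% with neither.

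Sox9 was found in 40.2, 26.5 and 19.5% of thinned mesenchymal cells, and in 58.4, 41.0 and 32.1% before thinning. Without thinning the share among Ebf2-positive cells was 56.3, 44.75 and 44.6%, and among Pparg-positive cells at E13.5 it was 73.7%. As background at the same 4000 UMIs, Sox9 was found in 2.29, 1.04 and 3.05% of erythroid-like cells, 7.32, 2.41 and 0.722% of macrophage-like cells and 8.13, 2.57 and 2.52% of spinal neuron-like cells. The median depths of these classes before thinning at E13.5 were 12460, 12168 and 6175 UMIs, against 9114.5 for brown adipose precursor-like cells.

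**Figure D2:**
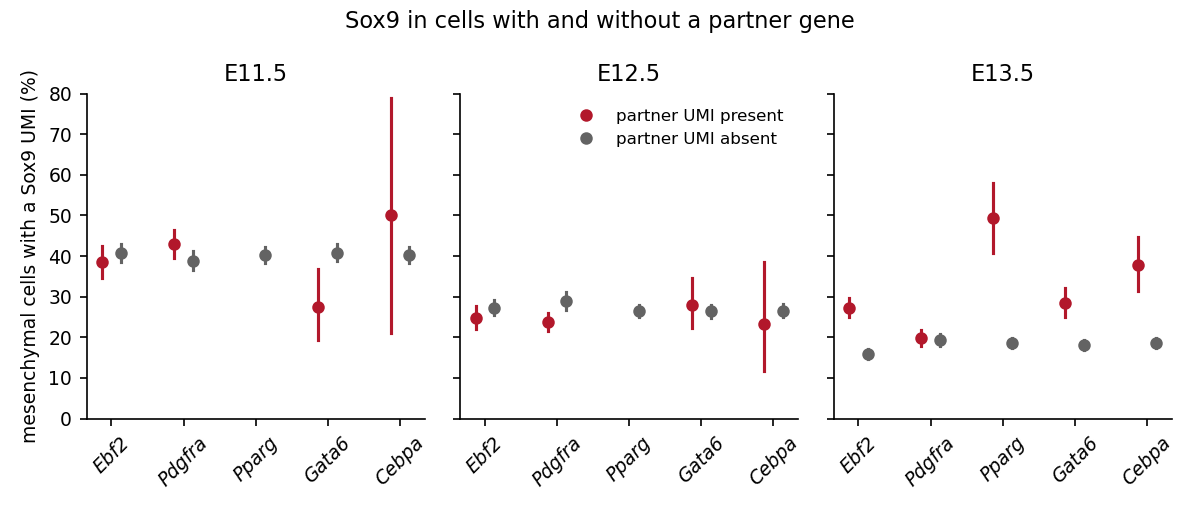
Percent of mesenchymal cells with a Sox9 UMI among cells with and without a partner gene, by stage, after thinning to 4000 UMIs, with exact 95% intervals; groups with fewer than 10 partner-positive cells are not drawn. At E13.5 Pparg-positive cells stand at 49.3% against 18.6%, and Ebf2-positive cells at 27.3% against 15.85%.

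Gene expression was next compared between E12.5 and E11.5 in the remaining mesenchyme, outside the chondrogenic-like and brown adipose precursor-like classes (2757 and 2424 cells), to follow the mesenchyme from which these tissues arise. At E12.5 the matrix and tendon lists were higher, with median log2 ratios of 2.07 and 1.64, and the S phase and G2 and M phase lists were lower, with −0.72 and −0.86. Sclerotome-like cells were 791 of the cells at E11.5 and 23 at E12.5, so the comparison was repeated without them, an alternative added after seeing the data. The other cells lay apart as well: 88.8% of them at E11.5 (1450 of 1633) and 91.6% at E12.5 were in sub-clusters with over 90% of their cells from that 1 of the 2 stages. The ratios therefore set different sub-clusters against each other and need not hold within cells of 1 kind. Ccl11, an eosinophil chemokine, was higher by 7.02 on the log2 scale (95% interval 5.65 to 8.90) and Aspn, a small proteoglycan, by 6.94 (5.89 to 8.25). Sox9 was lower by a log2 ratio of −1.24 (−1.29 to −1.18), from 248.2 to 105.3 CPM. Without sclerotome-like cells it was lower by a log2 ratio of −0.65 (−0.72 to −0.58), from 164.1 to 104.7 CPM, where the unnamed sub-cluster led by Pax9 and Pax1 (230 cells at E12.5, 146.6 CPM of Sox9) stayed in. Ebf2 was higher by 0.49 (0.43 to 0.56), Pdgfra by 0.83 (0.77 to 0.89), Gata6 by 1.12 (0.96 to 1.28) and Cebpa by 1.68 (1.17 to 2.21), and Prdm16 was at −0.81 (−1.03 to −0.60). Gata6 was at 0.57 (0.41 to 0.73) without sclerotome-like cells and at 0.54 (0.22 to 0.86) in cells with Xist and no Y-linked UMI. Pparg had 14 UMIs against 2, a log2 ratio of 2.75 (0.63 to 5.93).

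Further genes with the highest ratios were Serpinb1a (141 UMIs against 0), Ecrg4 at 7.001 (3 UMIs at E11.5, interval 5.44 to 9.29), Fezf2 at 6.64 (2 UMIs, 4.76 to 9.69), Lgals9 at 5.89 (3 UMIs, 4.32 to 8.18), Ctxnd1 at 5.72 (2 UMIs, 3.84 to 8.79) and Ranbp3l at 5.615 (4.24 to 7.50). Mexis was at 5.57 (3 UMIs, 3.99 to 7.86) and Shisa9 at 5.48 (3 UMIs, 3.90 to 7.77). The lowest were Afp, a serum protein of fetal liver and yolk sac (0 UMIs against 331), and Sall4 at −4.13 (−5.28 to −3.16), a factor of early embryonic cells. Gal was at −3.77, Pax3, a regulator of the dermomyotome, at −3.63, Msx2 at −3.03 and Msx1 at −2.83. Igdcc3 was at −2.91, Trim71, a regulator of developmental timing, at −2.71, and the serum amyloid genes Saa1 and Saa2, near-identical copies that can share reads, were at −2.91 and −2.70. Without sclerotome-like cells Saa1 and Saa2 were at −0.22 and −0.27, with intervals that include 0, Sall4 was at −2.71 and Afp had 0 UMIs against 1.

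By list, all 18 matrix genes measured were higher at E12.5, with a median log2 ratio of 2.07 above all 10000 random lists; Postn was at 3.64, Lox, which crosslinks collagen, at 3.24, Col6a1 at 2.96 and Dcn at 2.695. In the tendon list 9 of 10 were higher (median 1.64, percentile 100), led by Thbs4 at 5.03, the tendon glycoprotein Tnmd at 4.89, Kera at 2.65 and Col12a1 at 2.45. The IGF and imprinted growth list had 15 of 16 higher (1.07, percentile 100), with Igfbp3 at 2.63, Plagl1 at 2.455, Dlk1 at 1.69 and Meg3 at 1.61. Brown adipose regulators were higher in 12 of 16 (0.56, percentile 99.9), with Tbx15 at 1.695 and Cebpb at 1.535 beside Pparg and Cebpa. Lateral plate genes were higher in 9 of 13 (0.52, percentile 99.5), with Osr2 at 3.16, Pitx1 at 3.13 and Osr1 at 2.205, and a median of −0.06 (percentile 14.1) without sclerotome-like cells. Immediate early genes, which enzymatic dissociation also raises, were higher in 17 of 18 (1.39, percentile 100), with Nr4a1 at 2.15, Fos at 2.00, Klf2 at 1.86 and Atf3 at 1.745.

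Sclerotome genes were lower in 8 of 10 (median −0.70, percentile 0), with Uncx at −2.37, Nkx3-2 at −1.89 and Pax1 at −1.06, and Tbx18 at 1.13. The sclerotome-like class was named by these genes and lay almost wholly at E11.5, so the list follows that class and shows no difference within cells of 1 kind. Hox genes of groups 1 to 4, the most anterior, were lower in 11 of 12 (−0.54, percentile 0), with Hoxa4 at −1.14 and Hoxd4 at −1.025. The 20 S phase genes were all lower (−0.72, percentile 0), with Rrm2 at −1.45 and Cdc6 at −1.24, and so were the 20 G2 and M phase genes (−0.86, percentile 0), with Aurka at −1.17 and Ube2c at −1.14. Osteogenesis genes had a median of −0.16 (percentile 2.10), with Ibsp, a bone matrix protein, at 99 UMIs against 0 and Dlx5 at 1.68; Ibsp was at −0.52 when clustering left out marker genes. Heat shock genes stood at −0.27 (percentile 2.27), with Hspb1 at 1.64, hypoxia and glycolysis genes at −0.19 (4.05), with Eno1 at −1.15, and retinoic acid genes at −0.18 (6.47), with Cyp26a1 at 1.24.

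Posterior Hox genes had medians of 0.50 (groups 5 to 9, percentile 98.7) and 1.06 (groups 10 to 13, percentile 95.1), and myogenesis genes 1.08 (percentile 99.4), which became −2.97 when free RNA was subtracted. WNT response genes had a median of 0.38 (percentile 89.9), with Dkk2 at 2.375 and Sp5 at 2.275. Chondrogenesis genes went both ways (0.26, percentile 71.9), with Cnmd at 2.18, Matn4 at 1.99 and Col9a1 at −1.935, and so did dermomyotome and dermis genes (0.18, percentile 62.9). The medians of adipocyte differentiation (−0.01, percentile 12.2), Hedgehog (0.04, percentile 33.0), BMP and TGF-beta (0.02, percentile 39.0) and oxidative phosphorylation genes (−0.11, percentile 39.1) were no larger than the 0.16 by which TMM scaling moved this comparison. Ltbp1 was at 1.38, Bmp2 at 1.20, Cdon at 0.86 and Cox5a at −0.57. Thermogenic genes stood at 0.45 (percentile 46.9), over 6 members of low count.

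The same mesenchyme was compared between E13.5 and E12.5 (4110 and 2757 cells), the step at which brown adipose precursor-like cells were found in number. At E13.5 Clec3b was higher by 6.38 (95% interval 5.70 to 7.16), Ptgds, a prostaglandin synthase, by 6.24 and Dpt, a matrix protein of the dermis, by 5.015. The group held 965 dermal-like cells at E13.5 and 22 at E12.5, and 380 and 0 cells of the sub-cluster led by Clec3b, although clusters named dermal at the first level held 608 cells at E12.5. Sub-clusters with over 90% of their cells from 1 of the 2 stages held 37% of the E12.5 cells and 61.65% of the E13.5 cells. Sox9 was lower again, at −0.79 (−0.87 to −0.72), from 105.3 to 60.7 CPM. Pparg was higher by 3.90 (3.125 to 4.79), at 269 UMIs against 14, and Cebpa by 1.36 (1.08 to 1.64). The estimate of free RNA, likely too high at this stage, would account for 17.2 and 18.1% of the higher counts. Of the 269 Pparg UMIs, 120 lay in a sub-cluster led by H1f5, Esco2 and Mxd3 (18.03 CPM), 53 in the one led by Mfap5 and Clec3b (13.2), 36 in a dermal-like one (10.06) and 17 in one led by Ccnb2 and Cenpa (11.4). The other sub-clusters of at least 20 cells were at 0 to 4.37 CPM, so the Pparg ratio is not one of the whole group. Gata6 was higher by 0.87 (0.76 to 0.97). In cells with Xist and no Y-linked UMI, Cebpa was at 0.66 (0.24 to 1.115) and Gata6 at 1.71 (1.46 to 1.97). Ebf2 was at −0.32 (−0.38 to −0.27), or 0.073 when each library was clustered alone, Pdgfra at −0.56 (−0.61 to −0.51) and Prdm16 at −0.40.

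The WNT antagonists Sfrp5 at 4.73 and Sfrp4 at 3.63, the X-linked gene Xlr4a at 4.19, the immediate early gene Egr4 at 4.16, the tenascin gene Tnxb at 3.87 and Tspan8 at 3.43 were the other genes with the highest ratios. The lowest were Ibsp at −6.00 (2 UMIs against 99, −9.06 to −4.105; 1.95 when clustering left out marker genes) and Rnaset2b at −4.75 (−5.24 to −4.30), whose paralogue Rnaset2a can share its reads. Foxf1, the first leading gene of both sclerotome-like sub-clusters, was at −3.185 and Foxf2 at −2.49. Pcp4l1 was at −3.04, Tceal6 at −2.59, Car3 at −2.54, Nkx6-1 at −2.53, Adamts18 at −2.51 and Wscd1 at −2.42.

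Matrix genes were again higher in 18 of 18 (median 1.003, percentile 100), with Postn at 1.501, Dcn and Col14a1 at 1.45 and elastin (Eln) at 1.39. Immediate early genes were higher in 18 of 18 (1.23, percentile 100), with Nr4a1 at 2.75, Junb at 2.23, Atf3 at 2.13 and Klf2 at 1.88. Tendon genes had a median of 0.45 (percentile 99.99), where Egr2 at 2.05 and Egr1 at 1.299 are immediate early genes as well, and Thbs4 was at 1.18 and Tnmd at 1.17. Dermomyotome and dermis genes stood at 0.14 (percentile 97.2), with Dpt highest, Twist2 at 1.01 and Alx4 at −0.97. All 20 G2 and M phase genes (0.28, percentile 100) and 14 of 20 S phase genes (0.20, percentile 99.96) were higher, with Cdk1 at 0.58, Hmmr at 0.50 and Cdc6 at 0.49. Myogenesis genes had a median of 0.54 (percentile 99.98), which became −1.20 when free RNA was subtracted.

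Genes of cartilage, bone and sclerotome were lower at E13.5. The make-up of the group moved the same way. The unnamed sub-cluster led by Pax9 and Pax1 held 230 of 2757 cells at E12.5 and 179 of 4110 at E13.5, and sclerotome-like cells were 23 and 0. In the similar group of the Sox9 contrast, clusters named chondrogenic at the first level held 375 of 2538 and 316 of 4501 cells. These falls, and that of Sox9, therefore need not hold within cells of 1 kind. Chondrogenesis genes were lower in 13 of 14 (median −0.80, percentile 0), with Col2a1 at −2.18, Sox6 at −1.51, Sox5 at −1.50 and Col9a1 at −1.435. Sclerotome genes were lower in 8 of 9 (−1.18, percentile 0), with Uncx at −1.80, Foxc2 and Foxc1 at −1.55 and Pax1 at −1.24. Osteogenesis genes were lower in 8 of 10 (−1.06, percentile 0), with Msx2 at −1.59. Hox genes of groups 1 to 4 were lower in 11 of 12 (−0.78, percentile 0), with Hoxa4 at −2.02, Hoxa2 at −1.29 and Hoxa3 at −0.86. Lateral plate genes were lower in 11 of 13 (−0.36, percentile 0.265), with Lhx9 at −2.09, Tbx5 at −0.79 and Osr2 at 1.71. Retinoic acid genes were lower in 8 of 10 (−0.41, percentile 0.110), with Aldh1a2, the main enzyme of retinoic acid synthesis, at −1.585 and Cyp26a1 at −0.94.

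Brown adipose regulators were lower in 10 of 16 (median −0.28, percentile 1.01), although Pparg, Cebpb at 1.82, Cebpa and Gata6 were higher. Adipocyte differentiation genes had a median of −0.10 (percentile 54.4). Cd36, a fatty acid carrier also used by endothelium, was at 3.44 and Fabp4 at 1.496. The estimate of free RNA would account for 39.8 and 100% of their counts. With free RNA subtracted Fabp4 was at −6.35, a value set by the 0.5 UMIs added to each count. Thermogenic genes stood at 0.11 (percentile 79.9). Hypoxia and glycolysis genes were at −0.21 (percentile 4.44), with Adm at 1.01, and Hox genes of groups 5 to 9 and 10 to 13 at −0.25 (7.14) and −0.70 (2.78). Heat shock (0.01, percentile 72.2), Hedgehog (−0.10, 44.4), WNT (−0.00, 83.1), BMP and TGF-beta (−0.06, 56.3), IGF (−0.00, 53.2) and oxidative phosphorylation genes (−0.11, 9.045) had medians no larger than the −0.11 of TMM scaling here. Among them Hhip was at 1.11, Sp5 at 1.41, Tgfbi at −0.93, Bmp4 at −0.92, Plagl1 at 1.59, Dlk1 at 0.75, Igfbp5 at −0.65, Cdkn1c at 0.57 and Cox6c at −0.26.

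Mesenchymal cells with an Ebf2 UMI after thinning, outside the chondrogenic- and tendon-like classes, were also compared between stages (585, 759 and 1401 cells), to follow cells that hold a regulator of the brown adipose lineage. The group was added after seeing the data and its make-up differed with the stage, since 338 of its cells at E13.5, 16 at E12.5 and 0 at E11.5 were brown adipose precursor-like. Sclerotome-like cells, 791 in the whole mesenchyme at E11.5 and 23 at E12.5, were not left out of the group. The first-step values of Sox9, of somite genes and of the sclerotome list below are given with them only. These values need not hold within cells of 1 kind. In the group Sox9 was at −0.95 between E11.5 and E12.5 (95% interval −1.15 to −0.76) and at −0.12 between E12.5 and E13.5 (−0.31 to 0.07), an interval that includes no difference. Without the brown adipose precursor-like cells the second value was −0.59 (−0.81 to −0.37). Pparg had 0 UMIs at E11.5 and E12.5 and 86 at E13.5 (35 without those cells), and Cebpa was at 0.62 (−1.06 to 2.52) and then 2.65 (1.72 to 3.75). Gata6 was higher at both steps, at 0.85 and 0.88, Pdgfra was at 0.66 and −0.46, and Prdm16 at −1.02 and 0.26. TMM scaling shifted the second step by −0.11.

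At E12.5 the highest ratios in Ebf2-positive cells were those of Ly6h at 5.08 (4.085 to 6.30), Abi3bp at 4.74 (3 UMIs at E11.5, 3.15 to 7.04), Cxcl13, a lymphoid chemokine, at 4.68, Npy at 4.11, Nfix at 3.96, Ogn at 3.91, Cxcl14 at 3.79, Postn at 3.70, Eln at 3.445 and Agtr2 at 3.28. The lowest were the somite genes Uncx at −3.57, Foxc2 at −2.44, Tcf15 at −2.05 and Pax1 at −1.73, with Col9a1 at −2.23, Hsd11b2 at −2.18, Chd7 at −1.96, Zic1 at −1.92, Zic4 at −1.86 and Fli1 at −1.82. At E13.5 the highest were Clec3b at 6.33 (3 UMIs at E12.5, 4.78 to 8.62), Mfap5 at 3.03, Plac9 at 2.85, Cd44 at 2.81, Ren1 at 2.76, Abca8a at 2.68, Rbp4 at 2.67, Fgf2 at 2.655, Cebpa and Ccn3 at 2.51. The lowest were Pcp4 at −2.66, Col2a1 at −2.275, Runx2, a regulator of bone formation, at −1.96, Ephb1 at −1.94, Otor at −1.925, Crym at −1.88, Hmga2 at −1.85, Npy at −1.79, Fblim1 at −1.75 and Col25a1 at −1.71.

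In the same Ebf2-positive cells, brown adipose regulators had medians of 0.59 (percentile 99.5) and −0.02 (70.2), and adipocyte genes 0.33 (82.6) and 0.12 (93.7). Sclerotome genes had medians of −1.38 (percentile 0) and −0.69 (0.01), and chondrogenesis genes 0.26 (82.2) and then −1.32 (0). Immediate early genes stood at 0.91 and 0.79, each above all random lists. Only 3 thermogenic genes were measured at the second step (0.22, percentile 64.9).

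Chondrogenic-like cells at E13.5 (79 cells) were set against those at E12.5 (293). Sox9 was lower, at −0.77 (95% interval −0.92 to −0.62), while the chondrogenesis list stood at 0.06 (percentile 87.1). Car3, a carbonic anhydrase, was higher by 6.65 (5.88 to 7.54), Ecrg4 by 2.86, Hoxc8 by 2.70, Plac9 by 2.504 and Abi3bp by 2.40. Rnaset2b (0 UMIs against 121), Veph1 (0 against 116), Hmx1 at −3.12 (−4.35 to −2.13) and Uncx at −2.835 (3 UMIs, −5.13 to −1.25) were among the lowest. Ebf2 was at −0.62 (−1.20 to −0.09), Pdgfra at −0.04, Gata6 at −0.66 and Prdm16 at −0.06, with 0 UMIs of Pparg against 8 and 1 of Cebpa against 15. Immediate early genes stood at 0.50 (percentile 99.99). With marker genes left out of clustering, doublets kept or resolution doubled Ebf2 was at 0.56, 0.15 or 0.068, and Hmx1 was at 0.59 or 1.13 with each library clustered alone or resolution doubled.

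In myogenic progenitor-like cells (248, 256 and 379 cells), Barx2 was higher at E12.5 than at E11.5 by 5.02 (95% interval 4.13 to 6.09), Nfix, which drives the fetal muscle programme, by 4.28, Pitx1 by 3.96, Postn by 3.51 and Pxdc1 by 3.32. Meox2 was at −3.26, Hsd11b2 at −3.18, Nr2f1 at −2.99, Ntn1 at −2.84 and Thbs1 at −2.77. At E13.5, Col15a1 was at 3.88, Nppc at 3.41, Csgalnact1 at 3.09, Agtr2 at 2.91 and the peptide hormone gene Cck at 2.74. Col25a1, a collagen of muscle that motor axons need, was at −2.82, the myostatin antagonist Fst at −2.54, Fgf9 at −2.47, Nav2 at −2.39 and Cdo1 at −2.36. The myogenesis list had medians of 0.75 (percentile 100) and 0.02 (73.9), and immediate early genes 0.50 and 0.95 (both percentile 100). Sox9 was at −1.64 (−2.03 to −1.265) and −0.08, and Prdm16 at −0.27 and −1.08. Ebf2 was at −2.29 and 1.16 and Pdgfra at −1.59 and 1.19. By its estimate, likely too high, free RNA would account for all of the Ebf2 and Pdgfra at E13.5, and its subtraction gave −1.895 and −3.64. With doublets kept Pdgfra was at 0.052 at the first step.

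Myocyte-like cells (79, 179 and 269 cells) were 2 clusters. The one led by the sarcomere genes Tnnc1, Mylpf and Acta1 held 40, 31 and 33 of them, and the one led by Myog and Mymx held the others. In the class Barx2 was higher at E12.5 by 3.465, E2f2 by 2.25, Sirt2 by 1.83, Col9a1 by 1.82 and Nfib by 1.80. Myf6, a myogenic regulator, was at −8.24 (1 UMI against 120, 95% interval −13.6 to −5.735), Prss23 at −4.52, Meis2 at −4.19, Cadm1 at −3.73 and Crabp1 at −3.71. At E13.5, Cck was higher by 3.13, Itga6 by 2.39, Pde2a by 2.05, Sh3kbp1 by 1.96 and Fosb by 1.88, and Fst was at −4.07, the slow myosin gene Myh7 at −3.89, Col25a1 at −3.52, the sarcomere gene Tcap at −3.08 and St8sia2 at −2.17. In the cluster led by Myog alone, a comparison added after seeing the data (148 and 236 cells), Myh7 had 2 UMIs at E13.5 against 0 and Tcap none at either stage, so both genes lay in the other cluster, wholly for Tcap and but for those 2 UMIs for Myh7. Fosb was at −0.012 with each library clustered alone. Myogenesis genes had medians of −0.60 and −0.44 (both percentile 0). In the cluster led by Myog the second was −0.41 (percentile 0), while its 39 cells at E11.5 were too few for the first, which is not shown to hold within cells of 1 kind. The first became 0.22 with the other cell filter, 0.051 without marker genes and 0.22 with each library alone, and the second 0.70 with each library alone. Immediate early genes stood at −0.12 (percentile 39.2) and 0.88 (100), the latter at 1.415 in the cluster led by Myog. Sox9 was at 1.90 and −0.27; the first became −1.29, −1.37 or −1.36 with the other cell filter, without marker genes or with each library alone. Ebf2 was at 0.13 and 1.11, and the second became −0.49 at a 5% mitochondrial maximum and −1.95 with free RNA subtracted.

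The last comparison asked which genes go with Sox9 in mesenchymal cells outside the chondrogenic- and tendon-like classes, with Sox9-positive and Sox9-negative cells paired within each of the 3 libraries. Cells that the first level of clustering placed in clusters named chondrogenic (13, 375 and 316 cells) or tendon (20, 1249 and 871) stayed in the group of 2421, 2538 and 4501. Genes of cartilage formation rose in Sox9-positive cells. The type IX collagen genes Col9a3 (log2 fold change 2.65, SE 0.244), Col9a1 (1.77, SE 0.0928) and Col9a2 (1.35, SE 0.0962) rose together with Col2a1, the main cartilage collagen (1.69, SE 0.104), and Sox5, a partner of SOX9 (1.88, SE 0.159). Matn4 rose by 2.52 (SE 0.317), Wwp2, which hosts a cartilage microRNA, by 1.87 (SE 0.203), Mecom by 1.31 (SE 0.0924), Negr1 by 0.92 and Id4 by 0.85. Nrgn changed by −2.29 (SE 0.288), Vtn by −2.13, the WNT inhibitor Apcdd1 by −1.73 (SE 0.160), Arhgdib by −1.54, the WNT activator Rspo1 by −1.41, Crabp1, a retinoic acid carrier, by −1.205, the agouti gene a by −1.16, Aldh1a2 by −1.12, Efemp1 by −1.095 and Crip1 by −0.85. The rule that named these genes required the same sign in 3 of 3 libraries, so that agreement is no further evidence. Nrgn, Sp5 and Apcdd1 were leading genes of sub-clusters with Sox9 in 4.59 and 5.96% of cells before thinning. Vtn and Aldh1a2 led a meningeal-like one with 21.9%. These sub-clusters stayed in the group, so the contrast also sets kinds of cell against each other. Its differences, for genes and for lists, need not hold within cells of 1 kind.

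In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 12197 genes, 39 genes rose and 51 fell. In that test with that adjustment, the adjusted p was 0.00018 for Col9a1, 0.000366 for Col2a1, 0.00166 for Sox5, 0.0024 for Col9a3 and Apcdd1, and 0.0496 for Sp5, a WNT target whose fold change was −2.12. Prdm16 had a log2 fold change of 0.75 with the same sign in each library (0.84, 0.72 and 0.71) and did not pass (adjusted p = 0.0977 in edgeR with Benjamini-Hochberg adjustment). By the same edgeR test with Benjamini-Hochberg adjustment, Cebpa at 1.13 (adjusted p = 0.252), Ebf2 at 0.34 (0.442), Gata6 at 0.35 (0.664) and Pdgfra at −0.00 (0.997) did not pass either. Their ratios in E11.5, E12.5 and E13.5 were 0.57, −0.49 and 1.59 for Cebpa, −0.04, 0.15 and 0.82 for Ebf2, and −0.86, 0.45 and 0.79 for Gata6. Without the E11.5 library, Cebpa was at 1.26 (adjusted p = 0.0341 in edgeR with Benjamini-Hochberg adjustment) and Gata6 at 0.66 (0.00736). For Cebpa the libraries left in that fit had opposite signs, so its pass is not one shared by both. Pparg was too low to be tested.

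The numbers of genes that rose and fell depended on the libraries, at 140 and 230 without E11.5, 1 and 1 without E12.5, and 104 and 141 without E13.5. DESeq2 called 25 and 24 genes, edgeR without the library block 0 and 0 (70 and 89 at an unadjusted p under 0.05), edgeR without a filter 180 and 465, and cells with 2 or more Sox9 UMIs against 0 gave 73 and 105. Added after seeing the data, the fit without sclerotome-like cells gave 70 and 104 genes, 79 of the 90 among them. The fit without clusters named chondrogenic at the first level, also added later, gave 16 that rose and 40 that fell, 48 of the 90 among them. There Col9a3 rose by 2.27, Sox5 by 1.73, Col2a1 by 1.42 and Col9a1 by 1.36. Matn4 (1.80), Wwp2 (1.38), Id4 (0.67), Negr1 (0.60), the agouti gene a (−1.04), Sp5, Igfbp3 and Col6a2 did not pass in that fit. In cells with an Ebf2 UMI alone, 17 rose and 12 fell, of which 16 were among the 90. There Col2a1 rose by 1.38 and Igfbp3, an IGF-binding protein, fell by 0.90, and Gata6 was at 0.88 (adjusted p = 0.0748 in edgeR with Benjamini-Hochberg adjustment).

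**Figure D3:**
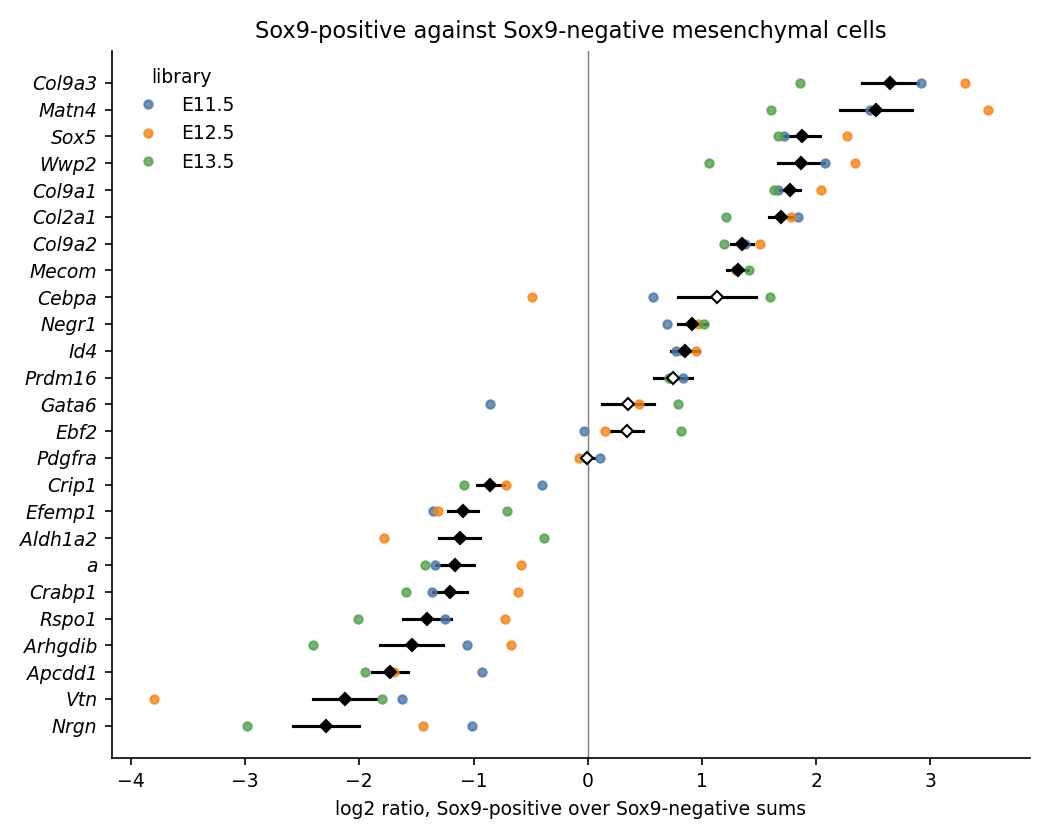
Log2 fold change of Sox9-positive over Sox9-negative mesenchymal cells; black diamonds with SE bars are the edgeR estimates of genes that passed, white diamonds genes that did not, and coloured dots the ratio in each library. Col9a3 stands highest at 2.65 and Nrgn lowest at −2.29, and Prdm16 at 0.75 did not pass.

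By list, 7 of 10 chondrogenesis genes rose (9 adjusted over the list alone) and none fell, and camera with its preset correlation gave an adjusted p of 1.19e-84 (adjusted p = 0.202 with an estimated correlation); Sox6 rose by 1.89. Of 13 BMP and TGF-beta genes 4 rose, the target genes Id4, Id2 (0.54), Id3 (0.50) and Id1 (0.30), and none fell (6 and 2 adjusted over the list alone; camera adjusted p = 2.19e-09, and adjusted p = 0.268 with an estimated correlation). Of 8 sclerotome genes 1 rose, Uncx at 1.51 (4 adjusted over the list alone; camera adjusted p = 8.835e-06, and adjusted p = 0.288 with an estimated correlation), with Pax1 at 0.96 and Foxc1 at 0.65 not past the test. Of 15 brown adipose regulators 1 rose, Ebf1 at 0.65 (3 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0394, and adjusted p = 0.348 with an estimated correlation).

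Hox genes of groups 1 to 4 and 5 to 9 were called higher by camera with no single gene past the test (adjusted p = 0.000384 and 0.0178; adjusted p = 0.2745 and 0.432 with an estimated correlation), with 2 genes and with 4 higher and 2 lower adjusted over the list alone. Hoxa4 was at 0.78, Hoxa5 at 0.60, Hoxb5 at 0.57 and Hoxd8 at −0.99. Osteogenesis genes were also called higher (adjusted p = 0.0248, and adjusted p = 0.432 with an estimated correlation), with 0 of 5 past edgeR's test over all genes or adjusted over the list alone. Without clusters named chondrogenic at the first level, camera called neither osteogenesis (adjusted p = 0.780) nor Hox groups 5 to 9 (adjusted p = 0.652).

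Lists called lower included dermomyotome and dermis, with 1 of 9 fallen (4 adjusted over the list alone; camera adjusted p = 2.15e-07, and adjusted p = 0.268 with an estimated correlation), where Crabp1 passed and Dkk1 at −1.53 and Twist2 at −0.86 did not. WNT response had 1 of 11 fallen, Sp5 (3 adjusted over the list alone; adjusted p = 3.89e-05, and adjusted p = 0.268 with an estimated correlation), with Notum at −1.86 and Nkd1 at −0.88. Matrix genes had 1 of 18 fallen, Col6a2 at −0.43 (1 rose and 7 fell adjusted over the list alone; adjusted p = 8.835e-06, and adjusted p = 0.288 with an estimated correlation). G2 and M phase (adjusted p = 6.7e-08, and adjusted p = 0.4535 with an estimated correlation) and oxidative phosphorylation (adjusted p = 0.0109, and adjusted p = 0.288 with an estimated correlation) were called lower with 0 of 20 and 0 of 15 genes past edgeR's test, either way of adjusting.

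Camera did not call the other lists. In retinoic acid (adjusted p = 0.219), 2 of 10 genes fell, Crabp1 and Aldh1a2 (3 rose and 3 fell adjusted over the list alone), with a median of 0.09 against a test direction of lower. In IGF and imprinted growth genes (adjusted p = 0.697), Igfbp3 fell by 0.74 (2 rose and 2 fell adjusted over the list alone), with a median of 0.08, again against a test direction of lower. Camera's adjusted p was 0.0559 for lateral plate (2 rose and 4 fell adjusted over the list alone, with Hand2 at −0.85), for S phase and for immediate early genes (1 rose and 2 fell adjusted over the list alone, with Nr4a1 at −0.79). It was 0.0764 for myogenesis, 0.150 for Hedgehog, 0.210 for Hox groups 10 to 13, 0.422 for hypoxia and glycolysis (2 fell adjusted over the list alone), 0.508 for adipocyte differentiation, 0.6225 for tendon (1 rose adjusted over the list alone) and 0.697 for heat shock. No thermogenic gene was high enough to be measured.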

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

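In this part the tests of the comparison group and of free RNA were chosen only after the results had been seen.

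Sox9 in brown adipose precursor-like cells stood below the other mesenchyme at E12.5, with a log2 ratio of −0.95, and above it at E13.5, with 1.51; the difference between the stages was not tested, since each stage is 1 library. Free RNA is argued against at E13.5, where the droplets without a cell held Sox9 at 29.99 CPM and the class at 193.9 (95% interval 182 to 206). For the E12.5 value a candidate explanation is the make-up of the comparison group, because without chondrogenic-, tendon- and sclerotome-like cells, which hold much of the Sox9 at that stage, the log2 ratio was −0.13 (−0.73 to 0.42), while at E13.5 it was 1.68. An unnamed sub-cluster rich in Sox9 (151 cells at E12.5) stayed in that group, so the value of −0.13 depends on the make-up as well. The stage of the embryos stays open as a biological explanation, untested, and so do the 24 cells behind the E12.5 value. Those cells held 0 Pparg UMIs (up to 13.05 CPM), against 42.3 CPM in the class at E13.5. It is therefore not shown that the class holds the same kind of cell at both stages.

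Gata6-positive mesenchymal cells held Sox9 in 27.5% at E11.5, against 40.8% of Gata6-negative cells, and in 28.5% at E13.5, against 18.0%, so the sign differed between stages of 1 library each and the difference was not tested.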

How the results depend on the processing

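In this part the class with the sub-cluster kept out, the comparison without chondrogenic-, tendon- and sclerotome-like cells, the fits and stage comparisons without sclerotome-like cells, the Ebf2-positive cells without brown adipose precursor-like ones, the myocyte-like cells of the larger cluster, the fit without clusters named chondrogenic at the first level and the fit in Ebf2-positive cells were chosen only after the results had been seen. Stage values rest on 1 library each, so the settings test the processing and not the stage, and depth limits classes of few cells such as the 24 brown adipose precursor-like cells at E12.5. Of 3108 stage ratios of named genes under the alternatives, 2377 stayed inside their counting interval, 710 moved and 21 reversed. Of 732 list medians 701 stayed, 23 moved and 8 reversed. Of 423 class shares 178 moved, of 345 Sox9 levels 128, of 688 shares of co-detection 210 and of 34 Sox9 ratios 15. Of 1374 values of named genes in the Sox9 contrast 1114 stayed, 124 newly passed the test and 91 no longer passed it. The other 45 changed sign, all in genes that had not passed the main test. Except where the text says otherwise, the cause was not tested.

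The share of brown adipose precursor-like cells at E12.5 (0.400%) was 0.134% at a mitochondrial maximum of 5%, 0.0815% with doublets kept, 0.133% without marker genes, 0.04997% at double resolution and 0% with each library clustered alone. At E13.5 (7.44%) it was 8.16% with the other cell filter, 8.49% at 5% mitochondrial, 1.70% with doublets kept, 1.62% with each library alone, 3.72% at double resolution and 12.8% with the sub-cluster kept out, which adds cells by construction. The Sox9 log2 ratio of the class at E13.5 (1.51) was 1.66 with doublets kept, 1.73 with each library alone, 1.71 at double resolution, 1.03 with the sub-cluster kept out and 1.68 without chondrogenic-, tendon- and sclerotome-like cells, and at E12.5 it was −0.13 in that last comparison.

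Thinning sets the share of cells with a UMI by construction. Sox9 in Ebf2-positive cells at the 3 stages was 29.7, 18.4 and 16.9% at 2000 UMIs and 56.3, 44.75 and 44.6% without thinning, and 45.3% at E11.5 at 5% mitochondrial. In Pparg-positive cells at E13.5 it was 33.3 and 73.7%.

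Sox9 in the remaining mesenchyme kept its direction in each setting. For E12.5 against E11.5 it was −1.43 with the other cell filter, −1.52 at 5% mitochondrial, −1.71 without marker genes, −1.17 with each library alone, −1.58 at double resolution, −1.40 with TMM and −0.65 without sclerotome-like cells. For E13.5 against E12.5 it was −0.92 at 5% mitochondrial, −0.59 with doublets kept, −0.64 without marker genes, −0.54 at double resolution, −0.68 with TMM and −0.66 with free RNA subtracted.

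Signs turned in some comparisons. Without sclerotome-like cells, for E12.5 against E11.5 in the remaining mesenchyme, the lateral plate median was −0.063. The sclerotome median there was 0.56, Pax1 0.83 and Nkx3-2 3.24 (7 UMIs against 0, so set by the 0.5 UMIs added), which leaving out cells named by these genes, nearly all at E11.5, brings by construction. The estimate of free RNA is likely too high at E12.5 and E13.5, so its subtraction may remove too much. With free RNA subtracted the myogenesis median in the remaining mesenchyme was −2.97 and −1.20 at the 2 steps, Fabp4 at E13.5 −6.35, Ebf2 and Pdgfra in myogenic progenitor-like cells at E13.5 −1.895 and −3.64, and Ebf2 in myocyte-like cells −1.95. Without marker genes Ibsp in the remaining mesenchyme was −0.52 and 1.95, Ebf2 in chondrogenic-like cells 0.56, and in myocyte-like cells at E12.5 the myogenesis median 0.051 and Sox9 −1.37. With each library alone Ebf2 in the remaining mesenchyme at E13.5 was 0.073, Hmx1 in chondrogenic-like cells 0.59, the myogenesis median in myocyte-like cells 0.22 and 0.70, Sox9 there −1.36 at E12.5 and Fosb −0.012 at E13.5. At double resolution Ebf2 and Hmx1 in chondrogenic-like cells were 0.068 and 1.13. With doublets kept Ebf2 there was 0.15 and Pdgfra in myogenic progenitor-like cells at E12.5 0.052. With the other cell filter the myogenesis median and Sox9 in myocyte-like cells at E12.5 were 0.22 and −1.29, and at 5% mitochondrial Ebf2 there at E13.5 was −0.49. In the larger myocyte-like cluster alone Myh7 at E13.5 was 1.97 (2 UMIs against 0, so set by the 0.5 UMIs added).

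In the Sox9 contrast (39 genes rose, 51 fell), DESeq2 called 25 and 24 genes, edgeR without a filter 180 and 465, cells with 2 or more Sox9 UMIs against 0 gave 73 and 105, the fit without sclerotome-like cells 70 and 104, the fit without clusters named chondrogenic at the first level 16 and 40 and the fit in Ebf2-positive cells 17 and 12. Leaving out 1 library gave 1 to 140 genes that rose and 1 to 230 that fell, the fewest without E12.5, with 2 pairs in each such fit. Both sums of a pair come from the same library, so the library was a replicate block, and without the block edgeR called 0 and 0 genes (70 and 89 at an unadjusted p under 0.05). Camera called 12 lists with its preset correlation and 0 with an estimated one. The 90 genes kept their sign in each setting that measured them, except that 69 of the 72 measured in Ebf2-positive cells did. The alternatives for the contrast within the brown adipose precursor-like class were not run, since that contrast could not be made.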

Other observations

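In this part the tests of free RNA and of doublets for Pparg-positive cells and the count of other splits were chosen only after the result had been seen, as were the genes and sub-clusters named in the next 2 paragraphs.

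Some genes of position along the body, picked after seeing the data, stood apart in brown adipose precursor-like cells at E13.5 from the other mesenchyme. Hoxa5, expressed from the neck backwards, was at 94.8 CPM (95% interval 86.5 to 104) against 32.3 (30.7 to 34.0), and Hoxc8, of the thorax, at 10.0 (7.47 to 13.2) against 58.2 (56.0 to 60.5), with Hoxc6 at 25.2 against 60.95, while Hoxa10 was at 12.6 (9.69 to 16.1) against 13.9 (12.9 to 15.05). Osr1, a gene of intermediate and lateral mesoderm, was at 204.9 against 137.4 and Emx2 at 34.2 against 23.3, while Tbx5 was at 18.1 against 26.8. Of the somite genes, Meox1 was at 30.5 against 42.7 and En1 at 33.0 against 45.4. Col2a1 was at 7.67 against 50.6 and Sox6 at 1.38 against 4.305, or against 14.5 and 3.098 in mesenchyme outside the chondrogenic-, tendon- and sclerotome-like classes, and Fabp4 was at 28.7 against 4.63. By its estimate, likely too high, free RNA would account for all of the Fabp4 count in the remaining mesenchyme at E13.5. Its part in the value of the class is not given. Ucp1, the thermogenic uncoupling protein, and Cidea had 0 UMIs in the 524 cells, which leaves up to 0.726 CPM for each.

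Sox9 was also high in an unnamed mesenchymal sub-cluster (151 cells at E12.5, 232 at E13.5), at 558.5 CPM (525 to 594) and 216.1 (198 to 235). It held Gata6 at 146.9 and 240.9, Acta2, a smooth muscle actin, at 469.0 and 1825.4, Pitx1 at 67.3 and 168.5, Runx1 at 201.4 and 224.4 and Hoxc8 at 107.4 and 213.4, with Ebf2 at 51.7 and 27.6 and Col2a1 at 66.8 and 13.8 CPM. Pitx1, Runx1 and Acta2, among the leading genes of this sub-cluster, also led a cluster named chondrogenic at the first level. Another unnamed sub-cluster, led by Msx1 and Zic4 (187 cells, all at E11.5), had Sox9 in 86.1% of cells before thinning, against 68.2% here. Outside the mesenchyme, mesothelium-like cells held 66.7 Sox9 CPM at E11.5 and 279.1 at E12.5 (226 to 340, 20 cells).

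Pparg-positive mesenchymal cells at E13.5 held Sox9 in 49.3% (40.7 to 57.9) against 18.6% of the others. Free RNA is argued against by erythroid-like cells, the background class with the highest upper bound, where 3.05% had Sox9 (0.838 to 7.63). Doublets with chondrogenic-like cells are argued against by Col2a1, at 7.14 CPM in Pparg-positive cells (1.95 to 18.3), where the extra Sox9 would have brought 535.5 CPM with it. That these cells transcribe Sox9 and Pparg together stays a hypothesis, found and tested in the same library, and a feature of that litter stays open.

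The 20 genes furthest apart at each step in the remaining mesenchyme were tested for causes other than stage. Sex is argued against for these sets of 20, since in cells with Xist and without Y-linked transcripts 19 of 20 kept the direction and at least 50% of the log2 ratio at the first step (all but Afp) and 19 of 20 at the second (all but Ibsp); outside the sets, Gata6 at the first step (0.54 for 1.12) and Cebpa at the second (0.66 for 1.36) kept the direction but less than 50%. A difference between litters or libraries could not be told apart from stage. It predicts the same shift in neuron-, muscle- and epidermis-like cells, which 3 of 20 genes showed at the first step (Sall4, Igdcc3 and Trim71, the 3 that could be measured in all of them) and 0 of 20 at the second (1 could be measured, Wscd1); the bound of fewer than 5 genes set beforehand as evidence against it was wrong, because most of the 20 are hardly present in the other types. Trim71 was at 0.779 against 5.105 CPM in mesenchyme and 2.36 against 15.1 in neurons, while Rnaset2b at E13.5 was at 1.31 against 16.0 in muscle and 0.419 against 31.0 in epidermis, so litter or strain may lie behind some of these genes as well as age.

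Beside the 90 genes called in the Sox9 contrast, 1 of the 10 splits of the 6 sums into 3 and 3, the real one, gave as many genes, and the highest of the others gave 1. Pairs of sums share a library, and the 3 other splits that part each pair gave 0, 0 and 1, while the rest put both sums of a library on one side. The splits are too few for a share under 0.05.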
